A study of Rattus norvegicus with 60 samples.

How the data were processed

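Liver RNA of male F344/N rats was profiled on 60 one-colour Affymetrix 3′ expression arrays. The labels define 12 groups of 5 arrays: for each of the 2 chemicals, a vehicle group and doses of 1, 6, 20, 60 and 120 mg/kg per day. Per the labels' protocols, the chemicals were given in corn oil by gavage at 2.5 ml/kg on 5 consecutive days, pieces of the left lateral liver lobe were flash-frozen, 100 ng of total RNA was amplified with the 3′ IVT Plus kit, and 12.5 µg of labelled product was hybridized for 16 hours. The protocol text spells out the dose series for DMPT, and the doses of the p-toluidine arrays were taken from their sample labels. The 5 replicates of a group are numbered in the titles, but the labels do not tie arrays to animals or cages, so p-values measure the spread between these samples.

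The deposited values were taken to be log2 expression values per probe set, and every fold given here depends on this. The scale was inferred from RMA (background correction, quantile normalization and probe set summarization, which gives log2 values), named without a version in the submitters' processing notes, and from the values, which ran from 0.0507 to 13.9. Some of them are lower than RMA usually gives, and its settings are not given in the sources used here. The arrays of the 2 chemicals appear to have been normalized separately: array medians ran from 3.53 to 3.61 over the DMPT arrays and from 2.73 to 2.81 over the p-toluidine arrays. Tests were therefore run within each chemical, where both sides of a contrast share a normalization. Expression levels cannot be compared across the chemicals, and responses (dose minus own vehicle) were compared in their place. RMA values carry no count or depth, and the number of arrays limits the precision.

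The value table held 31099 probe sets. Control probe sets (57) were left out and 31042 were tested, with no filter on brightness. Gene names came from the platform annotation, updated through gene IDs to the symbols of the RefSeq table of assembly GRCr8, which was used for names only, since the genome build behind the array annotation is not given in the sources used here. Exactly 1 symbol was attached to 20826 probe sets (20758 of them with a gene ID found in that table), several symbols to 436, and none to 9780. Probe sets with several symbols or none stayed in the tests and were not named. For statements on genes, each of 14217 genes was represented by the 1-symbol probe set with the highest mean over the 60 arrays.

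Differences were tested with limma 3.58.1 in R 4.3.3. For each chemical, the 30 arrays were fitted with 6 group means, and each dose was contrasted with its own vehicle group by moderated statistics (eBayes) with Benjamini-Hochberg adjustment over all probe sets of the contrast. A probe set was called at an adjusted p of at most 0.05, and "rose" and "fell" refer only to called changes. The difference between the responses to the 2 chemicals at equal dose (DMPT dose minus DMPT vehicle, minus p-toluidine dose minus p-toluidine vehicle) was tested in a fit of all 60 arrays with 12 group means. A trend over the rank of the dose was tested within each chemical. The series' design text names a comparison of vehicle with dose within each chemical by the ORIOGEN software at a false discovery rate of 5%. That software was not used here; an order-restricted isotonic test with 100 permutations was run as an alternative for the trends. The vehicle groups were also set against each other as a description of the gap between the array sets.

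Gene lists (32 lists of pathways, regulators' targets and liver cell types, each with at least 5 members on the array) were fixed before the data were examined, as were the contrasts, the rule for named genes and all alternatives that are not said to be added later. Lists were tested with camera with a preset correlation between genes of 0.01, adjusted over the lists of a contrast, and again with the correlation estimated from the arrays. The number of members called is given with adjustment over all probe sets and adjusted over the list alone. Several lists share members.

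The genes named in the text are the 10 largest called rises and 10 largest called falls at 120 mg/kg and in the difference at 120 mg/kg, the 5 largest in each direction at the other doses and between the vehicle groups, and up to 4 members of each list with the largest change at 120 mg/kg, whether or not they passed. Genes with a provisional symbol were not named. A gene named outside this rule is said to have been chosen after its values were seen.

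Errors of log2 changes are standard errors of the limma fit and errors of group means are standard deviations. Confidence intervals are 95% intervals from the fit. RNA quality was gauged by the difference between the 3′ and 5′ control probe sets of beta-actin and, as a second gauge, of Gapdh. Each was compared between dose and vehicle by two-sided exact permutation tests (20 tests over both gauges, Benjamini-Hochberg adjusted together). No array was identical to another: correlations between any 2 arrays of a chemical ran from 0.988 to 0.996 for DMPT and from 0.986 to 0.996 for p-toluidine.

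The procedure was tested on simulated data built from the real arrays' means and spreads, with 200 of 31042 probe sets changed by known factors. At 120 mg/kg of DMPT, 88.1% of the 1.5-fold changes, 98.5% of the 2-fold changes and 100% of the 4-fold changes were recovered, with 7 unchanged probe sets among 198 called. At 120 mg/kg of p-toluidine the shares were 91.0%, 98.5% and 100%, with 6 unchanged among 199. For the difference between the responses at 120 mg/kg they were 65.7%, 95.5% and 100%, with 9 unchanged among 183. The simulated noise was independent between probe sets, and the changed ones were drawn at random. These shares hold for that setting only, and genes with a larger spread between arrays can be missed at the same fold.

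The alternatives were a single fit of all 60 arrays, both vehicle groups together as control, a fit of only the arrays compared, leaving out dim probe sets, the replicate number as a block, quantile normalization over all 60 arrays, trended and robust variance priors, dose scores of log2(dose + 1), the order-restricted test, trends without the highest dose, the mean of all probe sets of a gene, the other probe sets of each named gene, and leaving out each array in turn. Leaving out 5 DMPT arrays with a narrow spread of values, and leaving out single arrays for the list tests and the correlation of the responses, were added after the data were seen. The 5 arrays had an interquartile range below 3.2, a limit used for DMPT only. The gap between them and the other DMPT arrays, 0.0805, was little wider than the next widest, 0.0786. Many p-toluidine arrays, with some in every group and in vehicle too, also lay below 3.2, down to 3.13, and were kept. The limit alone therefore does not mark an array as faulty.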

Results

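Messenger RNA levels were measured in the livers of male F344/N rats after 5 days of oral gavage with N,N-dimethyl-p-toluidine (DMPT), an aromatic amine used to speed the curing of acrylic bone and dental cements, or with p-toluidine, the same ring without the 2 methyl groups on the nitrogen. For each chemical, a corn oil vehicle group and groups given 1, 6, 20, 60 and 120 mg/kg per day were profiled, with 5 arrays per group and 60 arrays in all. Array medians ran from 3.53 to 3.61 on the log2 scale for the DMPT arrays and from 2.73 to 2.81 for the p-toluidine arrays, so levels are not comparable between the chemicals. The first principal component held 19.0% of the variance of the DMPT arrays and 20.0% of that of the p-toluidine arrays. The design compares each dose with the vehicle group of its own chemical, which shows at which doses changes were called and in which transcripts. The lowest dose with calls depends on the power of 5 arrays per group and is no threshold of effect. Changes are given as log2 differences from vehicle ± standard error of the limma fit, group means as mean ± SD, and n is 5 arrays per group throughout. Each named gene with a large change at a dose had all 5 dosed arrays on the same side of the vehicle mean unless stated otherwise.

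The largest rise at 120 mg/kg of DMPT was that of Gstp1, a pi-class glutathione S-transferase, which went from 6.11 ± 0.40 in vehicle to 12.02 ± 0.16, a change of 5.91 ± 0.34 or 60.1-fold (adjusted p = 2.43e-13). Akr7a3, an aldo-keto reductase that reduces aflatoxin aldehydes, rose by 3.69 ± 0.22 (12.9-fold, adjusted p = 4.08e-13), and Nqo1, a quinone reductase, rose from 6.15 ± 0.24 to 8.87 ± 0.54, by 2.72 ± 0.18 (6.59-fold). The aldo-keto reductase Akr1b8 (3.08 ± 0.39), the glutathione S-transferases Gsta3 (2.69 ± 0.39) and Gstt3 (2.47 ± 0.21), the cytochrome P450 Cyp1a1 (2.65 ± 0.35), the glutathione peroxidase Gpx2 (2.62 ± 0.20), the carbonic anhydrase Car2 (2.35 ± 0.17) and the reductase Ptgr1 (2.16 ± 0.11) completed the 10 largest rises. In all, 3043 of 31042 probe sets passed the test, 1326 higher and 1717 lower (2459, 1298 of them higher, without the 5 DMPT arrays of narrow spread), and they covered 1808 named genes. Of them, 535 changed at least 1.5-fold and 136 at least 2-fold.

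The largest fall at this dose was that of Mup5, a lipocalin of the urinary protein family, which went from 6.86 ± 1.79 to 3.14 ± 0.49, a change of −3.72 ± 0.76 (adjusted p = 0.00124). Obp3, of the same family, fell by 3.53 on that scale with an adjusted p of 0.0115, which became 0.0528 without vehicle replicate 2 and 0.0602 without the narrow arrays. The probe sets of both can also bind related family members. The stearoyl-CoA desaturase Scd changed by −2.68 ± 0.56 (adjusted p = 0.00155), the iron hormone hepcidin (Hamp) by −2.67 ± 0.45 (adjusted p = 0.000121), and the ornithine aminotransferase Oat by −2.11 ± 0.20. The serpin Serpinb9b fell as well (adjusted p = 0.000420). The vasopressin receptor Avpr1a changed by −1.85 ± 0.16, the taurine transporter Slc6a6 by −1.83 ± 0.24, the phosphate transporter Slc34a2 by −1.79 ± 0.30 and Cyp2c11, the main male-specific cytochrome P450 of rat liver, by −1.73 ± 0.39 (adjusted p = 0.00353). Single arrays lay apart from their group for Car2 (vehicle replicate 2 at 5.90, the others 6.24 to 6.35), Slc6a6 (vehicle replicate 2 at 7.83, the others 6.78 to 7.04) and Mup5 (120 mg/kg replicate 5 at 4.00, the others 2.80 to 3.10).

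Among the gene lists, the markers of preneoplastic liver foci, the glutathione S-transferases and the NRF2 targets shifted upward at 120 mg/kg of DMPT, and these 3 lists also passed with an estimated correlation. Of 28 NRF2 targets, which encode antioxidant and conjugating enzymes, 17 rose and 1 fell (18 and 2 adjusted over the list alone), with a median change of 0.54 (adjusted p = 4.1e-18, and 0.00747 with an estimated correlation). Of 19 glutathione S-transferases, 11 rose and 1 fell (13 and 2 adjusted over the list alone; median 0.51, adjusted p = 3.51e-13, and 0.0244 with an estimated correlation). Of 12 foci markers, 8 rose and none fell, with adjustment over the list alone too (median 1.61, adjusted p = 3.1e-13, and 0.000478 with an estimated correlation). The lists overlap: 5 foci markers are also NRF2 targets, Gstp1 and Akr7a3 among them.

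Cell cycle and DNA replication genes were called higher as a group with the preset correlation only, while Ccnd1, a G1 cyclin, was lower. Of 36 members, 16 rose and 1 fell (25 and 1 adjusted over the list alone; median 0.58, adjusted p = 7.83e-10, and 0.347 with an estimated correlation). The kinase Melk rose by 1.07 ± 0.16 and the topoisomerase Top2a by 0.99 ± 0.18, and Ccnd1 changed by −1.51 ± 0.19. The erythroid list also moved up, with 3 of 16 members rising (also 3 adjusted over the list alone; median 0.17, adjusted p = 0.0116, and 0.202 with an estimated correlation), among them the globin chaperone Ahsp (0.64 ± 0.13). Without the 5 DMPT arrays of narrow spread its adjusted p was 0.0551. Beside these groups, the 3′ minus 5′ difference of beta-actin, a gauge of RNA quality, was 1.28 ± 0.08 at 120 mg/kg and 1.48 ± 0.15 in vehicle (exact permutation p = 0.0159, adjusted p = 0.238 over 20 tests of beta-actin and Gapdh). The Gapdh difference was −0.103 ± 0.062 at 120 mg/kg and −0.035 ± 0.062 in vehicle (exact permutation p = 0.127). The narrow arrays were 1 at 6 mg/kg, 2 at 60 mg/kg and 2 at 120 mg/kg, with none among the vehicle arrays.

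The cytochrome P450 and conjugation lists split. Of 14 targets of the receptors CAR and PXR, 4 rose and 1 fell (the same numbers adjusted over the list alone; median 0.12, adjusted p = 0.00345, and 0.114 with an estimated correlation). The glucuronosyltransferase Ugt2b1 rose by 1.26 ± 0.13 and the retinal dehydrogenase Aldh1a1 by 1.24 ± 0.13, and Cyp3a9 changed by −1.56 ± 0.27. Of 16 members of the conjugation list, which leaves out glutathione S-transferases, 5 rose and 2 fell (5 and 4 adjusted over the list alone, median 0.11, adjusted p = 0.0134, and 0.0782 with an estimated correlation). Ugt2b7 was at 2.08 ± 0.18, the epoxide hydrolase Ephx1 at 1.18 ± 0.11 and the sulfotransferase Sult1c3 at −1.05 ± 0.18. The AhR target list did not pass (adjusted p = 0.191): of 8 members 2 rose, Cyp1a1 and Nqo1, and 1 fell, Cyp1a2, at −0.63 ± 0.11, again with the same numbers adjusted over the list alone.

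The male-biased, pericentral, acute phase, proteasome and stellate cell lists were called downward at 120 mg/kg of DMPT with the preset correlation. None of them passed with an estimated one. Of 10 male-biased liver genes 5 fell and none rose (7 fell adjusted over the list alone; median −0.44, adjusted p = 7.36e-05, and 0.202 with an estimated correlation), Mup5 and Obp3 with the largest changes. Of 17 pericentral hepatocyte genes 7 fell (7 adjusted over the list alone; median −0.21, adjusted p = 0.000191, and 0.139 with an estimated correlation), among them Oat and the gulonolactone oxidase Gulo (−0.57 ± 0.08). Of 23 acute phase genes 7 fell (11 adjusted over the list alone; median −0.14, adjusted p = 7.36e-05, and 0.0832 with an estimated correlation), among them A2m (−1.70 ± 0.34) and Apcs (−0.65 ± 0.07). Of 31 proteasome genes 10 fell by small amounts (14 adjusted over the list alone; median −0.16, adjusted p = 9.37e-06, and 0.347 with an estimated correlation), for example Psmd7 (−0.30 ± 0.06). Of 20 stellate cell and fibroblast genes 4 fell (4 adjusted over the list alone; median −0.22, adjusted p = 0.00123, and 0.347 with an estimated correlation), among them the matrix genes Ecm1 (−0.52 ± 0.09) and Col5a1 (−0.46 ± 0.08; a second probe set of similar brightness was at −0.08 ± 0.08, adjusted p = 0.644). Beta-actin's 3′ minus 5′ difference, given above, was lower in the same arrays (exact permutation test, adjusted p = 0.238), so their 3′ bias was smaller than in vehicle. Of these lists only the male-biased one was fitted with it as a covariate.

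The other lists did not pass at this dose. In the order of members called with all probe sets, 5 PPARA targets of 27 rose and 3 fell (6 and 4 adjusted over the list alone, adjusted p = 0.526). The fatty acid transporter Cd36 was at 1.15 ± 0.28 and the glycerol channel Aqp7 at 1.01 ± 0.22. Of 22 iron and heme genes 3 rose and 7 fell (4 and 8 adjusted over the list alone, adjusted p = 0.191); the transferrin receptor Tfrc rose by 1.54 ± 0.19 and heme oxygenase Hmox1 by 0.80 ± 0.12. Of 20 bile acid genes 1 rose, the exporter Abcc3 (2.04 ± 0.28), and 7 fell (1 and 9 adjusted over the list alone, adjusted p = 0.0689), among them Slc27a5 (−0.94 ± 0.13). This list was called downward with the mean of all probe sets of a gene (adjusted p = 0.0476), without 120 mg/kg replicate 1 (0.0443) and without 120 mg/kg replicate 2 (0.0302). Of 23 genes of gluconeogenesis and glycolysis 3 rose and 4 fell (4 and 5 adjusted over the list alone, adjusted p = 0.627). Of 20 fatty acid synthesis genes 2 rose and 4 fell (2 and 6 adjusted over the list alone, adjusted p = 0.627), with Scd and pyruvate kinase Pklr (−0.85 ± 0.14) among those that fell. Of 18 p53 and DNA damage genes 4 rose and 2 fell (likewise adjusted over the list alone, adjusted p = 0.191), with the death receptor Fas at 0.61 ± 0.11; without the narrow arrays this list's adjusted p was 0.0405. The clock gene Npas2 fell by 1.55 with a standard error of 0.15 and its partner gene Bmal1 changed by −0.44 ± 0.09, among 1 rise and 2 falls of 17 circadian genes (3 and 3 adjusted over the list alone, adjusted p = 0.876).

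No shift was called in the remaining lists at 120 mg/kg of DMPT. In the unfolded protein response list 1 of 24 rose and 3 fell (the same adjusted over the list alone, adjusted p = 0.526), the rise being Atf3 (1.52 ± 0.46), whose adjusted p was 0.128 without 120 mg/kg replicate 1. In the heat shock list 2 of 14 rose (2 adjusted over the list alone, adjusted p = 0.526), Cryab (0.35 ± 0.08) and Hspd1 (0.26 ± 0.06). Among 17 immediate early genes 2 rose (2 adjusted over the list alone, adjusted p = 0.795): Atf3 again, and Klf6 (0.56 ± 0.16), with an adjusted p of 0.103 without vehicle replicate 1. None of 22 cholesterol genes was called, in either adjustment (median 0.08, adjusted p = 0.627). Of 9 female-biased genes 1 rose, Fmo1 (0.57 ± 0.11), against 2 that rose and 1 that fell adjusted over the list alone (adjusted p = 0.340). Among the cell types, 1 of 17 Kupffer cell and macrophage genes rose (1 adjusted over the list alone, adjusted p = 0.626): Cd14 at 0.59 ± 0.17, with an adjusted p of 0.0775 without vehicle replicate 1. Of 17 lymphocyte genes 1 rose (none adjusted over the list alone, adjusted p = 0.550), Cd3d, with an adjusted p of 0.112 without vehicle replicate 5. None of 10 neutrophil genes (adjusted p = 0.726) or 16 sinusoidal endothelium genes (adjusted p = 0.627) was called in either adjustment. Of 13 cholangiocyte genes 3 rose and 1 fell (likewise adjusted over the list alone, adjusted p = 0.109), with an adjusted p of 0.0359 without 120 mg/kg replicate 1 and 0.0414 without replicate 3. Epcam was at 1.47 ± 0.13 and Anxa4 at 0.53 ± 0.09. Of 15 pancreatic acinar genes 2 fell (2 adjusted over the list alone, adjusted p = 0.627) among them Cela1 (−0.48 ± 0.12; adjusted p = 0.122 without the narrow arrays). Of 15 periportal genes 1 rose and 2 fell (3 and 2 adjusted over the list alone, adjusted p = 0.795). Igf1 was at −0.51 ± 0.09 and Asl at −0.37 ± 0.08. Median, mean and test differed in sign for the unfolded protein response, heat shock, immediate early, circadian and Kupffer cell lists.

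At 1 mg/kg of DMPT limma called 0 probe sets, with 1643 at an unadjusted p below 0.05 against 1552.1 by chance. At 6 mg/kg 52 were called, 17 higher and 35 lower (45 higher of 93 with quantile normalization over all arrays). The exporter Abcc3 rose by 1.56 ± 0.28 (adjusted p = 0.00917), Gstt3 by 1.32 ± 0.21 (adjusted p = 0.00182) and Gstm1 by 0.55 ± 0.08 (adjusted p = 0.00182). In a fit of only the arrays compared, Abcc3 had an adjusted p of 0.133 and Gstm1 one of 0.0804. The lipogenic regulator Thrsp changed by −1.15 ± 0.18 and the tumor necrosis factor receptor gene Tnfrsf9 by −0.78 ± 0.12, both with an adjusted p of 0.00182. The other 5 named calls at 6 mg/kg did not hold in every fit that left out 1 array. Mybl1 (−0.92 ± 0.20) was lost in all 10 such fits, with an adjusted p of up to 0.123 without vehicle replicate 3, and Akr7a3 (1.03 ± 0.22) in 9 of 10, with up to 0.188 without 6 mg/kg replicate 5. Adgrg2 (0.71 ± 0.15) was lost in 7, with up to 0.103 without vehicle replicate 2, and the cell cycle inhibitor Cdkn1a (−0.76 ± 0.15) in 5, with up to 0.0750 without vehicle replicate 1. Phlda3 (−0.75 ± 0.14), like Cdkn1a a p53 target, was lost in 1, with 0.0608 without vehicle replicate 4. The number of calls was 33, 30, 18 and 31 without vehicle replicate 1, 3, 4 and 5 in turn, and 31 and 23 without 6 mg/kg replicate 4 and 5.

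At 20 mg/kg of DMPT Gstp1 became the largest rise, by 4.16 ± 0.34 or 17.9-fold (adjusted p = 7.53e-09), from 1.52 ± 0.34 at 6 mg/kg (adjusted p = 0.0597). H19, an imprinted noncoding RNA, rose by 3.04 ± 0.53 (adjusted p = 0.00102), the stress gene Ddit4 by 1.79 ± 0.39, Gstt3 by 1.76 ± 0.21 and Abcc3 by 1.64 ± 0.28. Scd changed by −2.88 ± 0.56 (adjusted p = 0.00336) and Cyp3a9 by −1.44 ± 0.27 (adjusted p = 0.00254). Mup5 (−2.87 ± 0.76; 4 of 5 arrays below the vehicle mean) reached an adjusted p of 0.113 without vehicle replicate 2, and Serpinb9b (−1.58 ± 0.37) and Trim36 (−1.27 ± 0.32) reached 0.0596 and 0.0704 without 20 mg/kg replicate 1. In all 810 probe sets were called, 484 higher and 326 lower, and 499, 472 and 479 without vehicle replicate 3, 20 mg/kg replicate 2 and 20 mg/kg replicate 4. At 60 mg/kg 1613 were called, 600 higher and 1013 lower, against 1150, 695 of them higher, without the 5 narrow arrays (and 899 in a fit of only the arrays compared). Gstp1 was up 44.7-fold (5.48 ± 0.34), the stress transcription factor Atf3 by 2.47 ± 0.46, Akr7a3 by 2.35 ± 0.22, Gstt3 by 2.13 ± 0.21 and Gsta3 by 1.97 ± 0.39. Scd changed by −2.28 ± 0.56 (adjusted p = 0.0117, and 0.0730 in the fit of only the arrays compared), Hamp by −2.05 ± 0.45 and Serpinb9b by −1.67 ± 0.37, while Obp3 (−3.42 ± 0.92) and Mup5 (−3.05 ± 0.76) reached adjusted p-values of 0.0961 and 0.0533 without vehicle replicate 2, and 0.117 and 0.0743 without the narrow arrays.

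**Figure D1:**
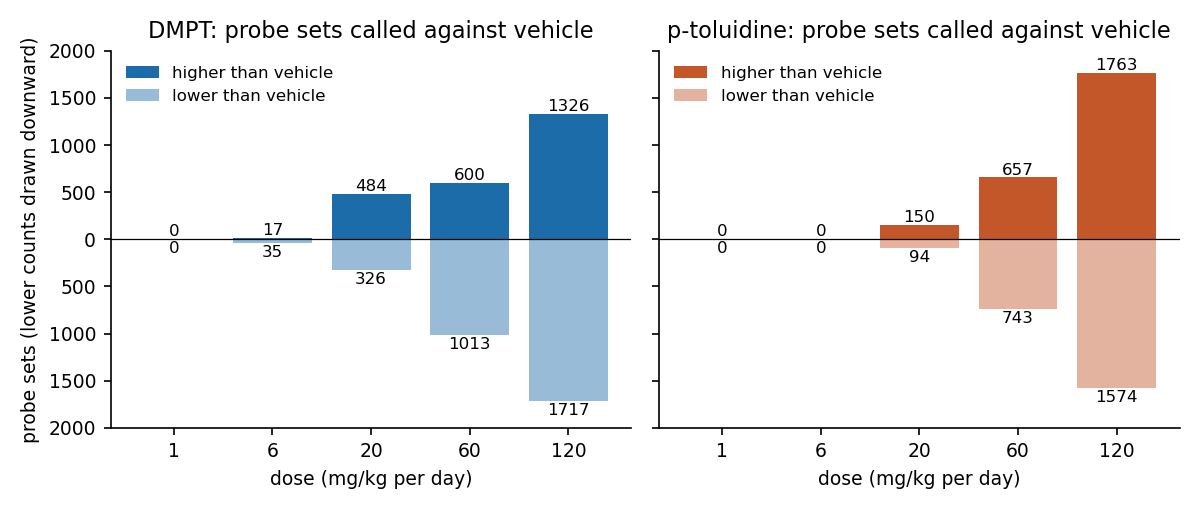
Number of probe sets called by limma at each dose (mg/kg per day) of DMPT and p-toluidine, higher and lower than vehicle, 5 arrays per group. The calls go from 0 at 1 mg/kg to 3043 for DMPT and 3337 for p-toluidine at 120 mg/kg.

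Of the lists, the glutathione S-transferases passed with an estimated correlation at the lowest dose. At 20 mg/kg of DMPT 9 of 19 rose (median 0.33, adjusted p = 8.67e-15, and 0.0374 with an estimated correlation) and at 60 mg/kg 10 rose (median 0.37, adjusted p = 0.0274 with an estimated correlation). Of the NRF2 targets 2, 7 and 13 rose at 6, 20 and 60 mg/kg and 0, 1 and 2 fell. The foci markers passed with an estimated correlation at 60 mg/kg (adjusted p = 0.0179). With the preset correlation 12, 12, 8 and 14 of the 32 lists passed at 1, 6, 20 and 60 mg/kg, against 0, 0, 1 and 2 with an estimated correlation.

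**Figure D2:**
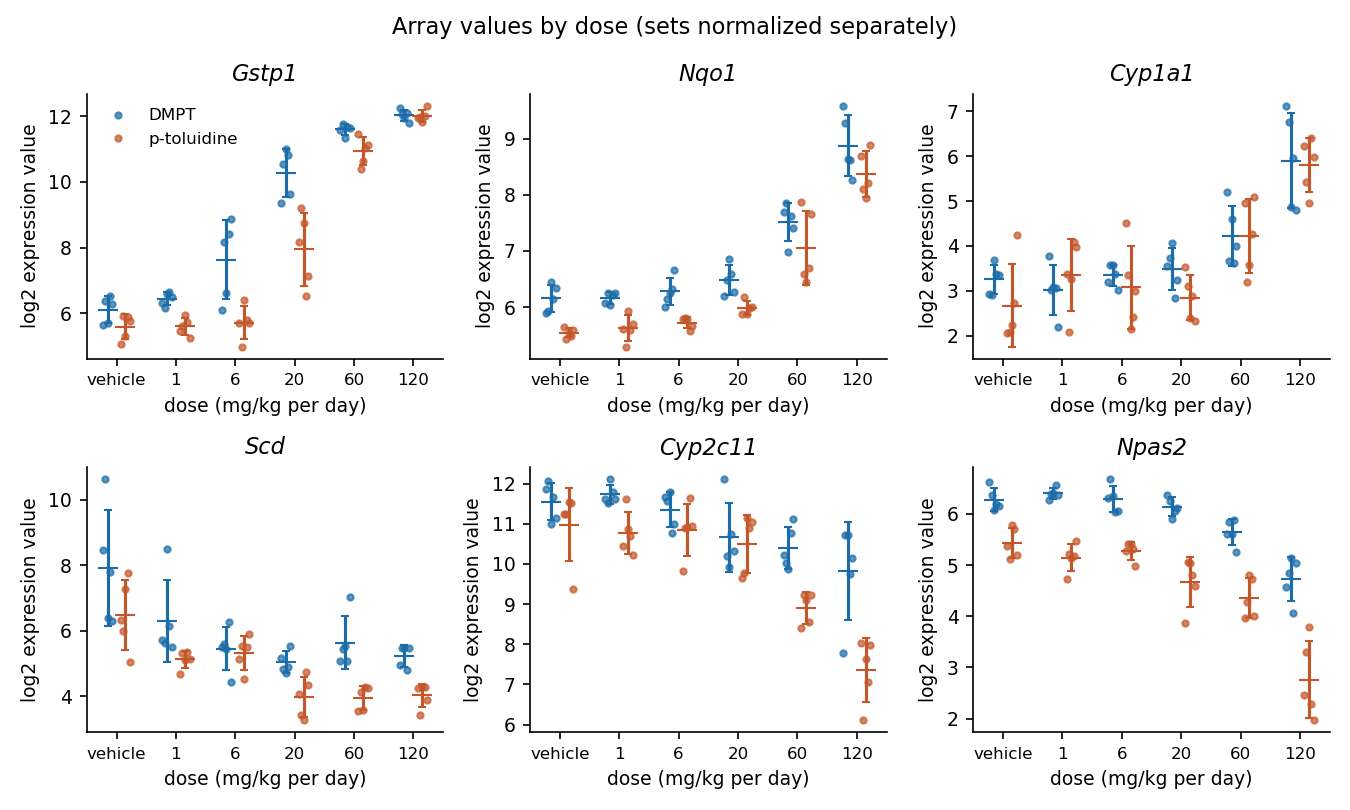
Log2 expression of Gstp1, Nqo1, Cyp1a1, Scd, Cyp2c11 and Npas2 against the dose (mg/kg per day) of each chemical, with points for single arrays and bars for mean ± SD (n = 5). Levels are not comparable between the chemicals; Gstp1 reached 12.02 at 120 mg/kg of DMPT from 6.11 in vehicle, and 12.00 at 120 mg/kg of p-toluidine from 5.60.

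Gstp1 was also the largest rise at 120 mg/kg of p-toluidine. It went from 5.60 ± 0.38 in vehicle to 12.00 ± 0.19, by 6.41 ± 0.32 or 84.8-fold (adjusted p = 7.35e-15). Akr7a3 rose by 4.22 ± 0.23 (18.7-fold), Akr1b8 by 4.15 ± 0.26 (17.8-fold), Cyp1a1 by 3.13 ± 0.44 (8.76-fold, adjusted p = 6.56e-06) and Nqo1 by 2.82 ± 0.19 (7.08-fold). Gsta3 (2.78 ± 0.29), Gpx2 (2.76 ± 0.19), Car2 (2.71 ± 0.18), the aldo-keto reductase Akr1b7 (2.61 ± 0.66, above the vehicle mean in 4 of 5 arrays) and Ptgr1 (2.59 ± 0.18) followed. In all 3337 probe sets were called, 1763 higher and 1574 lower, covering 2098 named genes, with 803 changed at least 1.5-fold and 206 at least 2-fold.

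Male-biased liver genes were among the largest falls at 120 mg/kg of p-toluidine. Cyp2c11 fell from 10.98 ± 0.91 to 7.36 ± 0.80, a change of −3.61 ± 0.39 (adjusted p = 5.98e-08). Mup5 changed by −4.48 ± 0.92 (adjusted p = 0.00103), Obp3 by −4.19 ± 1.05 (adjusted p = 0.00691), Dhrs7l1 by −3.39 ± 0.79 and the steroid dehydrogenase Hsd3b5 by −3.31 ± 0.84 (adjusted p = 0.0078). The estrogen sulfotransferase Sult1e1 changed by −2.96 ± 0.51, Slc34a2 by −2.90 ± 0.26, the methyltransferase Inmt by −2.87 ± 0.38, Npas2 by −2.67 ± 0.25 (adjusted p = 3.73e-09) and Oat by −2.49 ± 0.25. Vehicle replicate 5 lay below the other vehicle arrays for Cyp2c11 (9.37, the others 11.23 to 11.54), Mup5 (3.05, the others 7.32 to 8.24) and Sult1e1 (9.56, the others 11.28 to 11.67), and vehicle replicate 4 lay above them for Inmt (7.20, the others 4.07 to 4.96). Of 10 male-biased genes 9 fell (9 adjusted over the list alone; median −1.03, adjusted p = 1.31e-08, and 0.0491 with an estimated correlation). Of 9 female-biased genes 3 rose (3 adjusted over the list alone, adjusted p = 0.425), with Fmo1 at 0.54 ± 0.10 and Cyp2c12 at 1.87 ± 0.61, the latter with an adjusted p of 0.113 without vehicle replicate 2.

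The NRF2 targets, glutathione S-transferases, foci markers, male-biased genes and p53 targets passed with an estimated correlation. The male-biased genes and p53 targets passed only narrowly, both with an adjusted p of 0.0491, and these passes were not rerun without single arrays. Of the NRF2 targets 20 of 28 rose (21 adjusted over the list alone; median 0.64, adjusted p = 3.36e-24, and 9.28e-05 with an estimated correlation). Of the glutathione S-transferases 13 of 19 rose and 1 fell (14 and 1 adjusted over the list alone; median 0.59, adjusted p = 1.66e-14, and 0.00516 with an estimated correlation). Of the foci markers 8 of 12 rose (8 rose and 1 fell adjusted over the list alone; median 1.91, adjusted p = 5.16e-13, and 3.12e-05 with an estimated correlation). Of 18 p53 and DNA damage genes 5 rose (8 rose and 1 fell adjusted over the list alone; median 0.21, adjusted p = 0.00177, and 0.0491 with an estimated correlation), among them Ccng1 (0.77 ± 0.11) and the DNA repair gene Mgmt (0.72 ± 0.12). Cdkn1a, another member, was at 0.70 ± 0.23, with an adjusted p of 0.109 without vehicle replicate 5.

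Of 36 cell cycle genes 25 rose and 1 fell at 120 mg/kg of p-toluidine (32 and 1 adjusted over the list alone; median 0.75, adjusted p = 9.95e-14, and 0.159 with an estimated correlation). The replication helicase gene Mcm6 rose by 1.19 ± 0.27, the mitotic kinase Aurkb by 1.16 ± 0.23 and Pbk by 1.15 ± 0.29, and Ccnd1 changed by −1.08 ± 0.17. The proliferation marker Mki67 (1.33 ± 0.38) had an adjusted p of 0.0818 without vehicle replicate 5. Erythroid genes moved up too, with 2 of 16 called (2 adjusted over the list alone; median 0.10, adjusted p = 0.0349, and 0.265 with an estimated correlation), Slc4a1 at 0.62 ± 0.16 and Ahsp at 0.57 ± 0.13. That list's adjusted p was 0.0571 without vehicle replicate 1, 0.0942 without 120 mg/kg replicate 2 and 0.124 without 120 mg/kg replicate 4. Of 13 cholangiocyte genes 4 rose (4 adjusted over the list alone; median 0.09, adjusted p = 0.0124, and 0.0578 with an estimated correlation). Epcam was at 1.84 ± 0.12 and Anxa4 at 0.72 ± 0.07. Beta-actin's 3′ minus 5′ difference was 1.52 ± 0.09 at 120 mg/kg and 1.80 ± 0.15 in vehicle (exact permutation p = 0.0238, adjusted p = 0.238 over the same 20 tests), and that of Gapdh 0.077 ± 0.084 and 0.136 ± 0.033 (exact permutation p = 0.183).

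Stellate cell, pericentral, acute phase, bile acid and proteasome genes were called downward at 120 mg/kg of p-toluidine, beside the lower beta-actin difference, which means a smaller 3′ bias. Fits with that difference as a covariate were not run for these lists. None of these lists passed with an estimated correlation. Of 20 stellate cell and fibroblast genes 10 fell (12 adjusted over the list alone; median −0.33, adjusted p = 8.96e-06, and 0.120 with an estimated correlation), among them Reln (−0.49 ± 0.08) and Pdgfrb (−0.72 ± 0.11; its other, dimmer probe sets were at −0.06 and −0.03, not called). Of 17 pericentral genes 6 fell (6 adjusted over the list alone; median −0.14, adjusted p = 5.45e-05, and 0.120 with an estimated correlation), among them Oat and Lect2 (−0.76 ± 0.11). Of 23 acute phase genes 1 rose and 8 fell (1 and 12 adjusted over the list alone; median −0.17, adjusted p = 1.88e-05, and 0.0773 with an estimated correlation). A2m was at −1.98 ± 0.43 and Apcs at −1.04 ± 0.11. Of 20 bile acid genes 1 rose, Abcc3 (2.30 ± 0.31), and 8 fell (1 and 8 adjusted over the list alone; median −0.17, adjusted p = 0.00187, and 0.0878 with an estimated correlation). Slc27a5 was at −1.61 ± 0.15 and the uptake transporter Slco1a4 at −1.13 ± 0.12. Of 31 proteasome genes 4 fell (4 adjusted over the list alone; median −0.10, adjusted p = 0.00527, and 0.614 with an estimated correlation), with Psmd1 at −0.43 ± 0.10.

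Cholesterol genes and CAR and PXR targets were called upward at this dose, and both calls were lost on leaving out single arrays. Of 22 cholesterol synthesis and uptake genes 4 rose (7 rose and 1 fell adjusted over the list alone; median 0.26, adjusted p = 0.0154, and 0.667 with an estimated correlation), among them the lanosterol synthase Lss (0.74 ± 0.14). The adjusted p of the list was 0.148 without vehicle replicate 3 and 0.124 without 120 mg/kg replicate 4. Of 14 CAR and PXR targets 6 rose and 2 fell (likewise adjusted over the list alone; median 0.05, adjusted p = 0.0349, and 0.0773 with an estimated correlation). Aldh1a1 was at 1.37 ± 0.12 and Ugt2b1 at 1.29 ± 0.11. This list's adjusted p was 0.0680 without vehicle replicate 5, 0.0641 without 120 mg/kg replicate 2 and 0.0567 without 120 mg/kg replicate 4.

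The other lists were not called at 120 mg/kg of p-toluidine. Of 8 AhR targets 2 rose and 2 fell (likewise adjusted over the list alone, adjusted p = 0.786). Cyp1a2 was at −0.85 ± 0.13. Of 16 members of the conjugation list 5 rose and 4 fell (likewise adjusted over the list alone, adjusted p = 0.0807, and 0.0459 without vehicle replicate 3). Ephx1 was at 1.51 ± 0.11 and Sult1c3 at −2.02 ± 0.21. Of 27 PPARA targets 7 rose and 4 fell (7 and 6 adjusted over the list alone, adjusted p = 0.425). The thioesterase Acot1 was at 1.90 ± 0.32. Of 20 fatty acid synthesis genes 4 rose and 5 fell (4 and 6 adjusted over the list alone, adjusted p = 0.425): Scd changed by −2.45 ± 0.33 and the lipase Pnpla3 by 1.23 ± 0.27. Of 23 gluconeogenesis and glycolysis genes 4 rose and 5 fell (5 and 6 adjusted over the list alone, adjusted p = 0.815). Pck2 was at 1.07 ± 0.11 and Tat at −0.95 ± 0.23 (adjusted p = 0.0554 in the fit of all 60 arrays). Of 24 unfolded protein response genes 5 rose and 3 fell (5 and 5 adjusted over the list alone, adjusted p = 0.425). Atf3 was at 1.94 ± 0.48 and Sdf2l1 at 0.72 ± 0.15. In the heat shock list 1 of 14 fell (1 adjusted over the list alone, adjusted p = 0.622), Hsph1 at −0.74 ± 0.20, with an adjusted p of 0.0627 without 120 mg/kg replicate 2. Of 17 immediate early genes 2 rose (2 adjusted over the list alone, adjusted p = 0.128, with 0.0453 without vehicle replicate 3 and 0.0295 without 120 mg/kg replicate 1), Atf3 and Klf6 (0.83 ± 0.20). Of 17 circadian genes 3 rose and 2 fell (5 and 2 adjusted over the list alone, adjusted p = 0.438), with Nr1d2 at 0.87 ± 0.21, Bmal1 at −0.60 ± 0.09 beside Npas2 and, chosen after its values were seen, Dbp at 0.60 ± 0.13. Of 22 iron and heme genes 4 rose and 3 fell (4 and 5 adjusted over the list alone, adjusted p = 0.581). Hmox1 was at 0.77 ± 0.12. Of 17 Kupffer cell genes 2 fell (3 adjusted over the list alone, adjusted p = 0.0831), Cd5l at −0.49 ± 0.13 and Lyz2, the latter with an adjusted p of 0.152 without 120 mg/kg replicate 5. None of the lymphocyte (adjusted p = 0.786), neutrophil (adjusted p = 0.989) or sinusoidal endothelium genes (adjusted p = 0.128) was called in either adjustment. Of 15 acinar genes 2 fell (2 adjusted over the list alone, adjusted p = 0.146), with Cela1 at −0.84 ± 0.10, and of 15 periportal genes 3 rose and 2 fell (likewise adjusted over the list alone, adjusted p = 0.786). Cdh1 was at 0.48 ± 0.09 and Igf1 at −0.67 ± 0.12. Median, mean and test differed in sign for the AhR, conjugation, gluconeogenesis, circadian, female-biased and neutrophil lists.

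With p-toluidine the first calls came at 20 mg/kg. limma called 0 probe sets at 1 mg/kg and 0 at 6 mg/kg. At an unadjusted limma p below 0.05 there were 1992 and 2557, against 1552.1 by chance. The smallest adjusted p at 6 mg/kg was 0.0690, for Gstt3 at 1.01. Of the 30 genes called at 6 mg/kg of DMPT, 14 passed in the same direction at 6 mg/kg of p-toluidine when adjusted over those genes alone. The lack of calls at 6 mg/kg is therefore not a lack of change. Calls appeared without single arrays: 4 at 1 mg/kg without vehicle replicate 5, and at 6 mg/kg 4 without vehicle replicate 3 and 5 without 6 mg/kg replicate 1. At 20 mg/kg 244 were called, 150 higher and 94 lower. Gstp1 rose by 2.36 ± 0.32 (5.12-fold, adjusted p = 0.000166), Abcc3 by 1.65 ± 0.31, Akr7a3 by 1.61 ± 0.23 and Gstt3 2.82-fold (adjusted p = 3.21e-05). Scd changed by −2.50 ± 0.33 (adjusted p = 0.000166), the kinase Sgk1 by −1.59 ± 0.23 and the mitochondrial carrier Slc25a25 by −1.14 ± 0.20. Gsta3 (1.39 ± 0.29), Slc6a6 (−1.35 ± 0.29) and Slc34a2 (−1.20 ± 0.26) reached adjusted p-values of 0.0528, 0.0771 and 0.0855 without vehicle replicate 4. The number of calls was 139 and 115 without vehicle replicate 2 and 4, and 136, 124 and 152 without 20 mg/kg replicate 1, 2 and 3.

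At 60 mg/kg of p-toluidine 1400 probe sets were called, 657 higher and 743 lower (734 in a fit of only the arrays compared). Gstp1 was up 40.4-fold (5.34 ± 0.32), Akr7a3 by 2.97 ± 0.23, Gstt3 by 2.34 ± 0.17, Abcc3 by 2.19 ± 0.31 and Gsta3 by 2.12 ± 0.29. Mup5 changed by −4.14 ± 0.92 (adjusted p = 0.00568) and Scd by −2.51 ± 0.33. Obp3 (−4.01 ± 1.05) and Dhrs7l1 (−2.84 ± 0.79) reached adjusted p-values of 0.0742 and 0.0951 without vehicle replicate 3, and Hsd3b5 (−2.91 ± 0.84) 0.128 without 60 mg/kg replicate 4. With an estimated correlation, the glutathione S-transferases (adjusted p = 0.00893) and the CAR and PXR targets (adjusted p = 0.0163) passed at 20 mg/kg. At 60 mg/kg these lists (adjusted p = 0.00101 and 0.0124) passed together with the NRF2 targets (adjusted p = 0.00962) and the foci markers (adjusted p = 0.00126). With the preset correlation 3, 8, 9 and 14 lists passed at 1, 6, 20 and 60 mg/kg, against 0, 0, 2 and 4. Of the glutathione S-transferases 6 rose at 20 mg/kg and 12 at 60 mg/kg; of the NRF2 targets 7 and 12 rose and 0 and 1 fell.

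**Figure D3:**
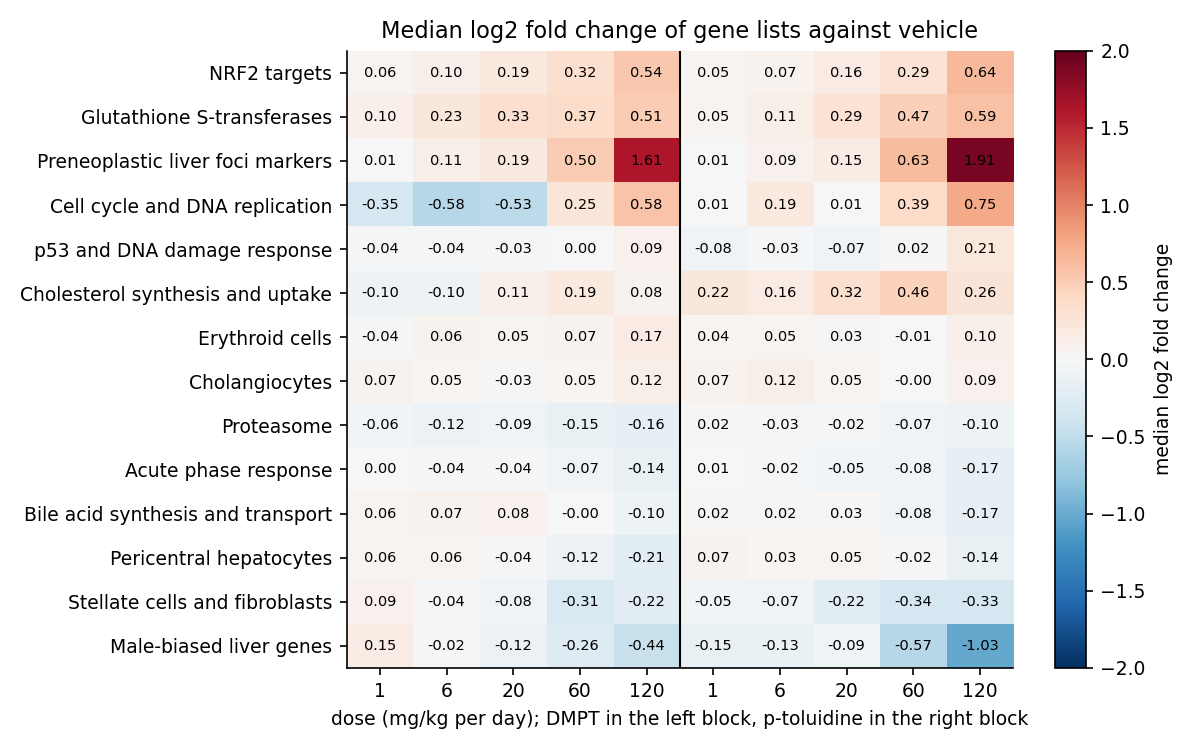
Median log2 change from vehicle of the members of 14 gene lists at each dose (mg/kg per day) of DMPT and p-toluidine, with colour showing direction and size. The median of the foci markers reached 1.61 for DMPT and 1.91 for p-toluidine at 120 mg/kg, and that of the male-biased genes −0.44 and −1.03.

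The responses to the chemicals with and without the 2 N-methyl groups were compared at doses equal in mg/kg, which are not equal in moles. The arrays of each chemical form their own set. A difference between the responses therefore cannot be told apart from a difference between the sets. At 120 mg/kg the log2 changes of 14217 genes correlated across genes with r = 0.816 (Spearman's rho 0.642), against 0.742 at 60, 0.466 at 20, 0.235 at 6 and 0.000173 at 1 mg/kg; genes are not independent replicates. Each chemical had its own vehicle arrays. At 120 mg/kg 522 genes rose with both chemicals, where independent lists would share 59.0, and 558 fell with both, where independent lists would share 73.0; 0 moved in opposite directions, where independent lists would share 135. At 60 mg/kg 183 rose and 268 fell with both (10.4 and 24.9 for independent lists), and at 20 mg/kg 52 and 16 (1.55 and 1.04). Of the 1808 genes called with DMPT at 120 mg/kg, 1334 passed in the same direction with p-toluidine when adjusted over those genes alone. In the other direction it was 1450 of 2098. Of 728 genes called only with DMPT 0 had a called difference between the responses, and of 1018 called only with p-toluidine 1 did.

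**Figure D4:**
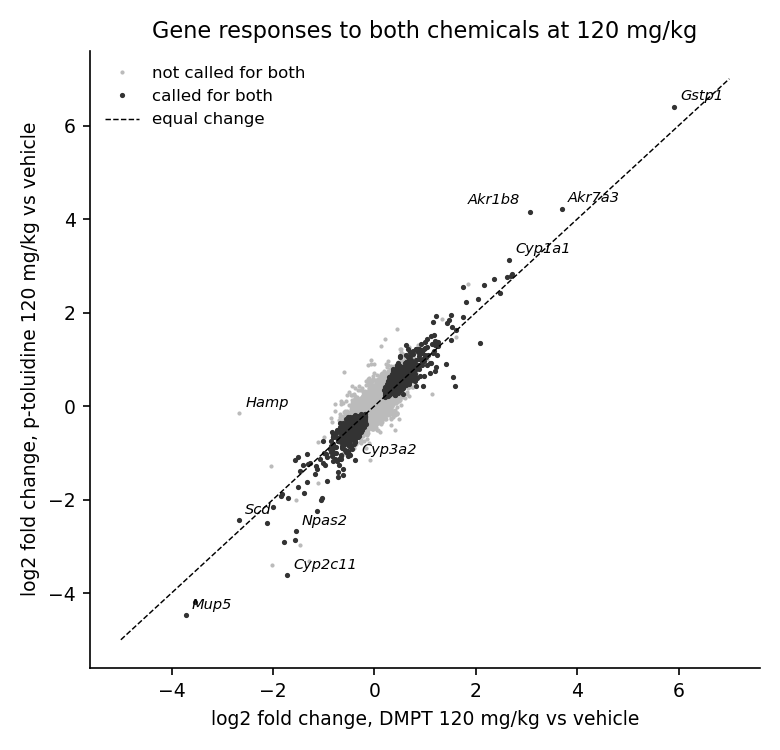
Log2 change from vehicle at 120 mg/kg per day of p-toluidine against that of DMPT, each point a gene (14217 genes). The changes correlated across genes with r = 0.816, and Gstp1 lies farthest up for both chemicals.

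A difference between the responses at 120 mg/kg was called for 2 probe sets, both of the Cyp3a family of cytochrome P450 enzymes. Cyp3a2, a male-biased form, was at −0.38 ± 0.08 with DMPT and −1.16 ± 0.09 with p-toluidine, a difference of 0.79 ± 0.12 (95% interval 0.55 to 1.02, adjusted p = 0.000455). Cyp3a23-3a1 was at −0.11 ± 0.09 with DMPT and −0.79 ± 0.10 with p-toluidine, a difference of 0.68 ± 0.13 (0.42 to 0.94, adjusted p = 0.0446). This call was lost in 13 of 20 fits that left out 1 array, with an adjusted p of up to 0.140 without p-toluidine vehicle replicate 4. The number of calls moved over 1.5 times in 17 of these 20 fits, from 1 to 8, with 8 without p-toluidine 120 mg/kg replicate 3 and 7 without DMPT vehicle replicate 5. A fit of only the arrays compared called 21, 17 of them higher with DMPT and 1 shared with the 2 above, and 39 at 20 mg/kg. At 1, 6, 20 and 60 mg/kg limma called 0 differences, with 2160, 1876, 2280 and 1488 probe sets at an unadjusted p below 0.05. Single arrays changed these zeros: 1 was called at 6 mg/kg without p-toluidine 6 mg/kg replicate 1, and 18 at 20 mg/kg without DMPT vehicle replicate 5. At 20 mg/kg 1 was also called without each of DMPT vehicle replicate 1, DMPT 20 mg/kg replicate 4 and p-toluidine 20 mg/kg replicate 2, and 3 at 60 mg/kg without DMPT 60 mg/kg replicate 1.

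The intervals leave room for sizable differences in other genes. DMPT minus p-toluidine at 120 mg/kg was −0.50 for Gstp1 (95% interval −1.49 to 0.49), −0.53 for Akr7a3 (−1.21 to 0.14), −0.10 for Nqo1 (−0.66 to 0.45), −0.48 for Cyp1a1 (−1.66 to 0.70), −0.23 for Scd (−1.61 to 1.15) and 0.04 for Gstt3 (−0.52 to 0.61). At 120 mg/kg 2059 probe sets had an unadjusted limma p below 0.05, against 1552.1 by chance, so many intervals excluded 0 without passing over all probe sets. From these, 4 genes were chosen after their values were seen: Akr1b8 (−1.08, −2.06 to −0.09, adjusted p = 0.701), Cyp2c11 (1.89, 0.72 to 3.05, adjusted p = 0.351), Npas2 (1.12, 0.51 to 1.73, adjusted p = 0.213) and Hamp (−2.52, −4.02 to −1.02, adjusted p = 0.332). At 20 mg/kg Gstp1 was at 4.16 with DMPT and 2.36 with p-toluidine, a difference of 1.80 (0.82 to 2.79, adjusted p = 0.231). Among the 32 lists, 6 differed at 120 mg/kg with the preset correlation, 2 higher and 4 lower with DMPT, and 3, 7, 4 and 5 at 1, 6, 20 and 60 mg/kg, against 0 at every dose with an estimated correlation. At 120 mg/kg the male-biased genes (median difference 0.70, adjusted p = 2.14e-05, and 0.329 with an estimated correlation) and Kupffer cell genes (0.17, adjusted p = 0.00620, and 0.560) lay higher with DMPT. The NRF2 targets (−0.22, adjusted p = 0.000115, and 0.329), p53 targets (−0.24, adjusted p = 0.0122, and 0.329), cell cycle genes (−0.26, adjusted p = 0.0311, and 0.762) and cholesterol genes (−0.16, adjusted p = 0.0351, and 0.706) lay lower. Of their members 1 male-biased gene was called, and adjusted over the list alone 2 male-biased genes were higher and 2 NRF2 targets lower.

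Trends over the dose rank were called for 4962 probe sets with DMPT (2140 upward and 2822 downward) and 4661 with p-toluidine (2414 and 2247). Without the 5 narrow arrays the DMPT number was 4361, with 2339 upward, so the larger share was then upward. Without the 120 mg/kg group the numbers were 2580 and 2018.

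The vehicle groups of the chemicals differed at 30295 probe sets, with a median difference of 0.65 toward the DMPT arrays, as separate normalization would give. After quantile normalization over all arrays, which removes that overall gap by construction, 6622 still differed. The array sets therefore also differ in ways beyond the overall gap. Beside that median, Hamp (2.47 ± 0.53), the clock gene Nr1d1 (2.21 ± 0.14) and the mitotic genes Cdkn3 (2.07 ± 0.37), Knstrn (1.95 ± 0.33) and Ccna2 (1.94 ± 0.37) were farthest up in DMPT vehicle. Lbh (−0.69), Tfrc (−0.62), Mettl7b (−0.53), Pfkl (−0.49) and Adrm1 (−0.47) were farthest down. These are levels across array sets and no effect of a chemical.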

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

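The tests by collection time, by a single vehicle array, by hepatocyte share, by blood or immune cells and by RNA quality as the whole source, the fits with the Gapdh difference as covariate, and the fits without the narrow arrays, were chosen only after the results were seen; the counts of other splits and the tests by RNA quality against a set share of the change were fixed before. The actin 3′ minus 5′ difference, the gauge of RNA quality used as a covariate, was itself related to 6134 probe sets with DMPT and 6158 with p-toluidine at an unadjusted limma p below 0.05, against 1552.1 by chance. After adjustment these were 1.37% of the probe sets with DMPT and 7.05% with p-toluidine, so the adjustment has less to act on in DMPT.

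Among 80 groups of arrays of 26 genes with large changes, 9 held a single array far from the other 4, where about 4 would by chance, since chance sets apart about 1 in 20 groups. With DMPT, vehicle replicate 2 was at 5.90 for Car2 (the others 6.24 to 6.35) and at 7.83 for Slc6a6 (6.78 to 7.04), and 120 mg/kg replicate 5 was at 4.00 for Mup5 (2.80 to 3.10). With p-toluidine, vehicle replicate 5 was low for 3 genes: 3.05 for Mup5 (7.32 to 8.24), 9.37 for Cyp2c11 (11.23 to 11.54) and 9.56 for Sult1e1 (11.28 to 11.67). Vehicle replicate 4 was at 7.20 for Inmt (4.07 to 4.96), 120 mg/kg replicate 3 at 4.70 for Slc34a2 (3.86 to 4.08), and 120 mg/kg replicate 5 at 1.87 for Mup5 (2.36 to 2.49). The responses to the 2 chemicals at 120 mg/kg differed by test for Cyp3a2 (0.79 higher with DMPT) and Cyp3a23-3a1 (0.68 higher with DMPT).

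The first pattern weighed is the low clock gene Npas2 at 120 mg/kg, −1.55 with DMPT and −2.67 with p-toluidine. RNA quality is argued against: with the actin 3′ minus 5′ difference as a covariate the change was −1.45 (95% interval −1.83 to −1.08) and −2.66 (−3.31 to −1.998). A shift in collection time stays open: the partner gene Bmal1 moved the same way by less, −0.44 (−0.62 to −0.25) and −0.60 (−0.80 to −0.41), and some clock output genes of the opposite phase were higher. Of Nr1d1, Nr1d2, Dbp, Tef and Hlf, only Hlf was called higher with DMPT (0.51). With p-toluidine these were Nr1d2 (0.87), Dbp (0.60) and Tef (0.33). A response of this gene to the chemicals may be the source, which these arrays cannot separate from the time of collection.

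The second pattern is the fall of male-biased liver genes at 120 mg/kg, with array-level means of −1.18 with DMPT and −1.91 with p-toluidine. Adjusting for the actin difference gave −1.18 (−1.95 to −0.42) with DMPT and −1.99 (−2.87 to −1.10) with p-toluidine, which argues against RNA quality as the whole source for both. Neither change shrank with this covariate. With the Gapdh difference the DMPT change was −0.92 (−1.61 to −0.22). A partial contribution stays open for DMPT, because its interval without a covariate (−1.85 to −0.50) was already too wide for this test to decide. Leaving out any 1 vehicle array left falls of at least −0.98 and −1.74, so no single high vehicle array is the whole source; p-toluidine vehicle replicate 5, which is low, makes the fall smaller (−2.25 without it). A lower share of hepatocytes as the whole source would raise the lists of the other liver cell types together. Stellate cell genes moved down instead, by −0.22 (−0.40 to −0.03) and −0.27 (−0.43 to −0.11), which argues against it for both chemicals. Cholangiocyte genes moved up, by 0.20 (0.04 to 0.35) and 0.23 (0.10 to 0.35). They were the only one of these lists with an interval wholly on the upper side. Markers of other cell types can also change by regulation, so these values do not decide on a partial contribution from the share of hepatocytes. For p-toluidine a loss of male-type expression may be a response to the chemical, as a hypothesis, from which a part due to fewer hepatocytes was not told apart. For DMPT a part that comes from RNA quality cannot be told apart from it either.

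The third pattern is the higher level of cell cycle genes at 120 mg/kg, with array-level means of 0.49 (0.054 to 0.92) with DMPT and 0.72 (0.31 to 1.13) with p-toluidine. With the actin difference as a covariate the p-toluidine mean was 0.76 (0.30 to 1.23), which argues against RNA quality as the whole source. A part stays open, because the interval without the covariate was already too wide to decide on it, and the mean did not shrink. The DMPT mean moved toward 0, to 0.25 (−0.18 to 0.68), and to 0.33 (−0.12 to 0.77) with the Gapdh difference, and RNA quality stays open there. Of the blood and immune cell lists the erythroid genes moved highest, by 0.18 (0.08 to 0.28) and 0.17 (0.07 to 0.27), and their member Ahsp rose by 0.64 and 0.57, so more blood cells stay open for both chemicals. More dividing cells in the dosed livers may account for the pattern, which stays open for both chemicals.

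Other splits of the arrays into groups of the same sizes were drawn, 100 in each case with the real one included. A chance division of the arrays is argued against where the real split gave more calls than every other. For DMPT this held at 6 mg/kg (1 split with as many calls, the real 52 against 12 in the highest other), 20 mg/kg (1 split, 810 against 21), 60 mg/kg (1 split, 1613 against 81) and 120 mg/kg (1 split, 3043 against 293). For p-toluidine it held at 20 mg/kg (1 split, 244 against 9), 60 mg/kg (1 split, 1400 against 1031) and 120 mg/kg (1 split, 3337 against 610). The splits cannot address cages, which the labels do not give. The 52 calls at 6 mg/kg of DMPT fell to 15 in a fit of only the arrays compared. The split with 1031 exchanged 1 array of each group. The trends had 1 split each as large (4962 against 21 and 4661 against 1), the vehicle groups 1 (30295 against 26021), and the correlation of the responses at 120 mg/kg 1 (0.816 against 0.739). Where 0 calls were made every split gives as many by construction, which says nothing on chance: this holds for all 100 splits of DMPT at 1 mg/kg (highest other 11), p-toluidine at 1 mg/kg (65) and 6 mg/kg (26), and the differences at 1 mg/kg (8), 6 mg/kg (7), 20 mg/kg (20) and 60 mg/kg (1176). For the difference at 120 mg/kg 8 of 100 splits gave as many as the real 2, with up to 1621. The splits of a difference exchange dosed and vehicle arrays within a chemical and so carry the dose effects, a structure of the samples that the 1176 and 1621 calls show, and they decide nothing about chance for that count.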

How the results depend on the processing

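The fits without 5 DMPT arrays of narrow spread, and leaving out single arrays for the list tests and the correlation, were chosen after the data were seen; the other settings were fixed before. No called change of a named gene and no list test reversed. The balance of calls did turn over without the narrow arrays, from mostly lower to mostly higher: 695 of 1150 were higher for DMPT at 60 mg/kg, 1298 of 2459 at 120 mg/kg, and 2339 of 4361 trends pointed upward. It also turned for p-toluidine at 60 mg/kg with only the arrays compared (377 of 734 higher, against 657 of 1400). The cause was not tested. Of 232 called changes of named genes, 177 passed in every setting run on the same probe sets, 46 were lost on leaving out some single array and 41 in another setting, 8 of them under the replicate block. Of 81 other probe sets of genes with called changes, 75 had the same direction and 49 were also called. Those not called include a dimmer probe set of Mup5 for both chemicals, of Fas, Klf6 and Smad7 for DMPT, and of Nr1d2, Pnpla3, Reln, Cdh1, Slc4a1 and Tfrc for p-toluidine. Among the list tests, 625 of those leaving out 1 array gave the call as reported, 8 lost and 7 gained one. These used the preset correlation only. Pooling both vehicle groups was run for the counts and not for single genes.

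Counts outside 1.5 times those reported were the following; the cause was not tested unless stated. With only the arrays compared, 15 were called for DMPT at 6 mg/kg, 899 at 60 mg/kg, 2, 133 and 734 for p-toluidine at 6, 20 and 60 mg/kg, and 1, 39 and 21 for the differences at 6, 20 and 120 mg/kg. Without dim probe sets the counts were 101 (DMPT, 6 mg/kg), 390 (p-toluidine, 20 mg/kg), 2 (difference, 20 mg/kg) and 15110 (vehicle groups, where fewer probe sets were tested). Quantile normalization over all arrays gave 93 (DMPT, 6 mg/kg), 1 (p-toluidine, 6 mg/kg) and 6622 (vehicle groups, whose overall gap it removes by construction). The trended and robust prior gave 83 for DMPT at 6 mg/kg, and the fit of all 60 arrays 392 for p-toluidine at 20 mg/kg. Trends without the 120 mg/kg group, with fewer arrays, numbered 2580 and 2018. Without the narrow arrays 1 difference was called at 120 mg/kg. An estimated correlation left 3 of 12 lists for DMPT and 5 of 15 for p-toluidine at 120 mg/kg. With both vehicle groups as control the counts were 21818, 22685, 19992, 21292 and 20754 for DMPT and 22047, 21541, 21379, 21402 and 21082 for p-toluidine at 1 to 120 mg/kg, which by construction carries the gap between the array sets.

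Replicate numbers did not pair the arrays: deviations of same-numbered arrays correlated from −0.308 to 0.322, and not every array correlated best with its own number. With the replicate block 1 probe set was called for p-toluidine at 6 mg/kg, 1 for the difference at 20 mg/kg and 1 at 120 mg/kg, and the other counts stayed within 1.5 times.

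Leaving out 1 array at a time gave 18 to 73 calls for DMPT at 6 mg/kg and 472 to 666 at 20 mg/kg, and 0 to 4, 0 to 5 and 115 to 247 for p-toluidine at 1, 6 and 20 mg/kg. The differences at 6, 20, 60 and 120 mg/kg ranged over 0 to 1, 0 to 18, 0 to 3 and 1 to 8. With 5 arrays per group, precision is limited by their number.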

Other observations

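The observations below were chosen after the values were seen, and no explanation was tested for them. Hepcidin (Hamp), the liver hormone that limits iron release into blood, stepped down with the dose of DMPT: −0.62, −1.26, −1.37, −2.05 and −2.67 at 1, 6, 20, 60 and 120 mg/kg, called at 60 and 120 mg/kg (adjusted p = 0.00463 and 0.000121, all 5 arrays below the vehicle mean). With p-toluidine it was at −0.27, 0.23, −1.35, −0.81 and −0.15, with no call. Smad7, an inhibitory partner of the pathway that drives Hamp, moved with it under DMPT (−0.68 ± 0.12 at 60 mg/kg and −0.83 ± 0.12 at 120 mg/kg), and Tfrc, which imports iron, moved the other way (0.93 ± 0.19 and 1.54 ± 0.19). With p-toluidine at 120 mg/kg Smad7 was at −0.34 and Tfrc at 0.62, the latter with an adjusted p of 0.0985 without 120 mg/kg replicate 1. The vehicle groups of the chemicals also stood apart for Hamp, by 2.47 against a median of 0.65 over all probe sets, and for Tfrc the other way, by −0.62. Levels are not comparable across the array sets, so whether the vehicle rats differed in these genes is not known. For Hamp the difference between the responses did not pass at 120 mg/kg (−2.52, 95% interval −4.02 to −1.02, adjusted p = 0.332).

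H19 and the stress gene Ddit4 had their largest estimated change at a middle dose of DMPT. The doses were not tested against each other, so a peak there is not told apart from the spread between arrays. H19 was at 1.14, 2.03, 3.04, 1.84 and 1.61 over the 5 doses, and Ddit4 at −0.21, 0.56, 1.79, 1.64 and 0.69. With p-toluidine H19 was at 1.07, 1.54, 1.83, 1.90 and 1.48, and Ddit4 at 0.31, 0.10, 0.29, 0.83 and 1.26, none of them called.

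For cell cycle genes the median change of the 36 members was −0.35, −0.58, −0.53, 0.25 and 0.58 at 1, 6, 20, 60 and 120 mg/kg of DMPT. No dose passed with an estimated correlation (adjusted p = 0.520, 0.216, 0.531, 0.756 and 0.347), against 7.09e-14, 2.99e-19, 6.44e-12, 0.0359 and 7.83e-10 with the preset one. Over all probe sets 0, 0, 4, 1 and 1 members fell and 0, 0, 0, 1 and 16 rose; adjusted over the list alone 0, 23, 16, 1 and 1 fell and 0, 0, 0, 1 and 25 rose. With p-toluidine the medians were 0.0065, 0.19, 0.0091, 0.39 and 0.75 over the same doses, with adjusted p-values of 0.945, 0.890, 0.942, 0.591 and 0.159 with an estimated correlation. The mitotic genes Cdkn3, Knstrn and Ccna2 were also among the largest excesses of DMPT vehicle over p-toluidine vehicle, by 2.07, 1.95 and 1.94, on levels that are not comparable across the array sets.

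Cholesterol genes were raised over several doses of p-toluidine. Of 22 members 4 rose at 20 mg/kg (median 0.32, adjusted p = 3.7e-09, and 0.257 with an estimated correlation) and 9 at 60 mg/kg (median 0.46, adjusted p = 2.65e-11, and 0.140 with an estimated correlation), against 4 at 120 mg/kg. Stellate cell genes were lower at 60 mg/kg too, with 9 of 20 falling with p-toluidine (median −0.34, adjusted p = 0.0574 with an estimated correlation).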
